A study of Mus musculus with 24 samples.

How the data were processed

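Messenger RNA was sequenced from HL-1 cells, a beating cell line derived from mouse atrial cardiomyocytes. Per the labels' protocols, the cells were transduced with adenovirus at 30 infectious units per cell (MOI). The virus carried a short hairpin RNA against MuRF1, the protein of the Trim63 gene, or a scrambled hairpin. After 48 h, the cells were stretched by 15% at 1 Hz for 60 min or left unstretched. The labels call the stretch uniaxial in one place and biaxial in another, so its geometry is left open here. RNA was extracted with TRIzol directly afterwards, and libraries were made with a stranded poly(A) capture kit.

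The samples fell into 4 groups of 6 by their titles. These are control and MuRF1 knockdown cells, each non-stretched and stretched. The labels do not say that replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Each library code holds a number that is the same within a group and differs between groups, and the labels do not say what it stands for. If it marks a plate or a batch, that batch and the group cannot be told apart.

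The authors deposited a table of estimated counts for 20351 protein-coding genes, in which 36.6% of values were whole within a tolerance of 1e-09. The submitters' processing notes name kallisto 0.44.0, DESeq2 1.18.1, R 3.4.4 and the GRCm38.p6 build. The annotation release and the tool that summed transcripts to genes are not given in the sources used here. A second table deposited by the authors holds a normalized signal for the same genes. Its ratio to the raw count was not 1 factor per library but varied between genes, with a median coefficient of variation of 2.97%. There, 77 genes stood at 0 in all libraries, against 0 genes in the raw table. The normalized signal was used only as an alternative scaling.

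Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled with TMM factors. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14411 genes. A robust quasi-likelihood model with 1 coefficient per group was fitted to all 24 libraries, so that the groups shared 1 estimate of the spread with 20 residual degrees of freedom. Log2 fold changes are given with their standard errors (SE). Benjamini-Hochberg adjustment covered all tested genes of a comparison, with a threshold of 0.05. The comparisons were stretch in control cells, stretch in knockdown cells, knockdown without stretch, knockdown with stretch, and the interaction, which is the difference between both stretch responses. Levels are CPM after TMM scaling, as mean ± SD. The Trim63 level was also compared with a two-sided exact permutation test.

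Before the data were examined, 39 lists of pathways, complexes and cell type markers were written down, together with the design, the alternatives and the rule for naming genes. With at least 3 measured members required, 38 lists were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera was run again with an estimated correlation, and fry was run beside it. Each list is also described by how many members passed edgeR's test over all genes, and over the list alone. The rule named Trim63 and its relatives Trim55 and Trim54. It also named the 8 largest rises and 8 largest falls per comparison among genes past the threshold with an average log2 CPM of at least 1, without clone names. It further named the 2 members with the smallest adjusted p in the leading direction of each list that passed or had 3 members called. A comparison with fewer than 5 calls had all of them named, plus the 3 genes with the smallest p.

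Gene positions were taken from GENCODE release vM21 on GRCm38, in which 18431 of the 20351 symbols were found. Transcript length and GC content were known for 93.1% of the tested genes. A 3' UTR of at least 50 bases was annotated for 13148 of them, 91.2%. Genes of near-identical families can share reads, and how the authors' counting divided these is not stated. Whether the counting used strand is not stated either, so antisense genes are given as uncertain.

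The test was checked on counts simulated from the real means and library sizes. For stretch in control cells, with 14411 genes in the step, edgeR recovered 53.7% of genes changed 1.2-fold, 80.6% of those changed 1.5-fold and 80.3% of those changed 2-fold, and 5.92% of the calls were false. For the interaction the recovered shares were 46.3%, 70.1% and 87.9%, with 4.90% false calls. The simulated genes varied independently, with no outlying library and no bias by GC content or length. These shares may thus not hold for the real comparisons. The 60 pairs of replicates within groups were compared, and the lowest chi-square per gene was 2.85, so that no pair came near sampling noise and none had identical values.

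The alternatives fixed in advance were DESeq2 size factors, no filter, a filter of 1 CPM in 6 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, the replicate number or the letter of the library code as a block, only the groups compared, and each library left out in turn. Further alternatives were chosen after the data were seen. They leave out the 2 outlying libraries, which are stretched control replicate 5 and non-stretched knockdown replicate 4, use the authors' factors as offsets, or remove a smooth of GC content and transcript length from each library with natural splines of 4 degrees of freedom. The list tests were also run without stretched control replicate 5, in camera with the preset correlation only. No sample was left out of the main results. No hairpin sequence is given in the sources used here, so target sites within Trim63 were not mapped.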

Results

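Gene expression was measured by poly(A) RNA sequencing in 24 libraries of HL-1 cells, 6 in each of 4 groups. Control cells carried a scrambled hairpin and knockdown cells a hairpin against MuRF1, a muscle-specific ubiquitin ligase that binds the sarcomere. Each kind of cell was either left unstretched or stretched cyclically for 60 min. The series title states the purpose, which was to find the part MuRF1 plays in the transcriptional response of cardiomyocytes to stretch. Libraries held 23.6 to 54.8 M estimated counts, and all but stretched control replicate 5 held at least 37.7 M.

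Knockdown and control libraries separated completely on the first principal component, which held 44.6% of the variance and ran from -33.1 to -23.5 in knockdown libraries and from 24.6 to 29.9 in control libraries. The second component held 10.2% and was led by a single library, stretched control replicate 5, at 54.7 against -14.9 to 13.2 in the other 23. That library also had the lowest share of mitochondrially encoded transcripts, at 1.45% of counts against 2.49% to 3.67%. Its ribosomal protein transcripts took 3.27% of counts against 4.31% to 4.97%, and its replication-dependent histone transcripts stood at 491 CPM against 189 to 277 CPM. It was kept in all main results, and counts without it are given beside them.

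Trim63, the gene targeted by the hairpin, was far lower in every knockdown library than in any control library. It lies on chromosome 4 at 134315120 to 134329629 on the plus strand of GRCm38 (ENSMUSG00000028834) and has 9 exons. Without stretch its level was 55.7 ± 1.17 CPM in knockdown cells and 640 ± 68.1 CPM in control cells (SD, n = 6 each), 91.3% lower. With stretch it was 68.5 ± 7.91 CPM against 781 ± 81.7 CPM (SD, n = 6 each), 91.2% lower. Each exact permutation test gave p = 0.00216, the smallest that the 924 divisions of 12 libraries allow. The design text gives the knockdown at protein level as more than 50%, which is not tested by these data.

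Trim55, which encodes the related ligase MuRF2, also fell with the knockdown. Its level was 16.6 ± 0.543 CPM against 33.6 ± 0.837 CPM in control cells without stretch, and 19.0 ± 1.47 CPM against 34.0 ± 2.04 CPM with stretch (SD, n = 6 each). The log2 fold changes were -1.01 (SE 0.0454, adjusted p = 7.99e-17) and -0.84 (SE 0.045, adjusted p = 5.26e-15). Trim55 lies on chromosome 3 at 19644474 to 19692421 (ENSMUSG00000060913). Trim54, which encodes MuRF3, was too low to be tested, with group means of 0 to 0.667 counts. Stretch raised Trim63 in both kinds of cell, by 0.29 on the log2 scale (SE 0.0718, adjusted p = 0.0174) in control cells and by 0.30 (SE 0.0754, adjusted p = 0.0129) in knockdown cells. The interaction was 0.01 (SE 0.104, adjusted p = 0.988), and its sign turned with no filter, with limma-voom and without the 2 outlying libraries.

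**Figure D1:**
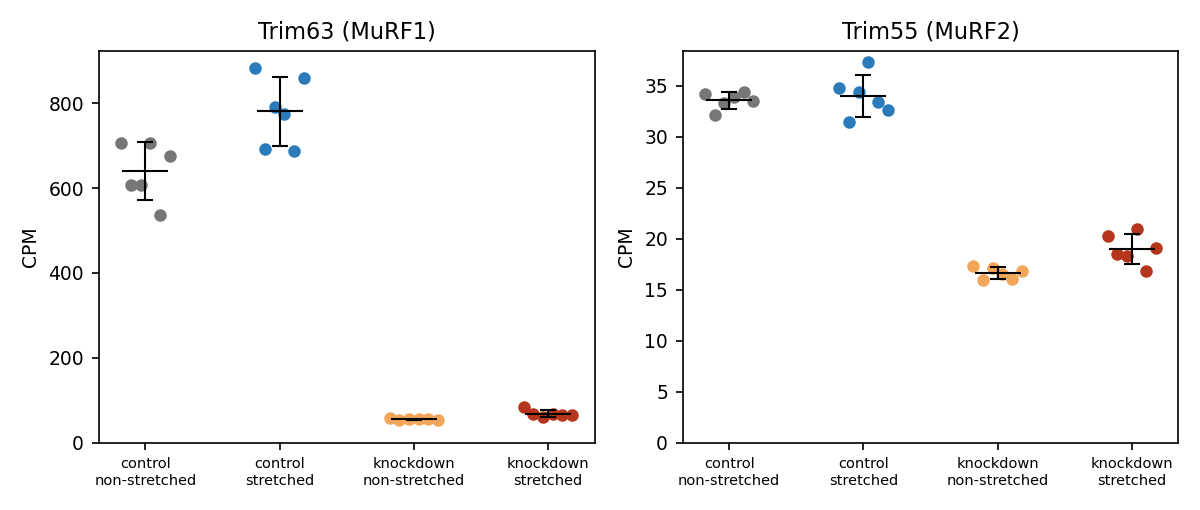
Trim63 and Trim55 in CPM (vertical axes) for each of the 24 libraries, by group; points are libraries and bars are the mean with the SD of 6. Trim63 lay at 640 and 781 CPM on average in control cells and at 55.7 and 68.5 CPM in knockdown cells, and Trim55 was also lower in both knockdown groups.

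Stretch of control cells for 60 min raised several genes that respond rapidly to growth and stress signals. Jun, a subunit of the AP-1 transcription factor, stood at 93.0 ± 11.3 CPM in stretched and 57.5 ± 10.5 CPM in non-stretched control cells (SD, n = 6 each), a log2 fold change of 0.69 (SE 0.105, adjusted p = 0.000344). Dusp8, a phosphatase that acts on stress-activated MAP kinases, rose from 46.9 ± 5.20 to 78.0 ± 6.01 CPM (SD, n = 6 each, adjusted p = 2.13e-08). Ankrd1, a cardiac ankyrin repeat protein of the sarcomere, rose by 0.62 on the log2 scale (SE 0.0679, adjusted p = 3.21e-06). Wnt9a, a Wnt ligand, fell by 0.67 (SE 0.0704, adjusted p = 1.41e-06). Txnip, an arrestin-like inhibitor of glucose uptake, fell from 240 ± 20.7 to 180 ± 16.2 CPM (SD, n = 6 each, adjusted p = 8.63e-05).

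In all, 857 of 14411 genes passed in control cells, of which 368 rose and 489 fell, with a median absolute log2 fold change of 0.185. Only 19 rose and 1 fell more than 2-fold, and the rule for naming genes left these out for low counts or clone names. Besides Jun and Dusp8, large rises were those of Apol8 (0.97, SE 0.211, adjusted p = 0.00683), the tight junction gene Cldn15 (0.86, SE 0.129, adjusted p = 0.000162), the olfactory receptor Olfr635 (0.72), Slfn1 (0.67) and the lysosomal membrane gene Cln3 (0.67). Besides Wnt9a, the largest falls under that rule were those of the homeobox genes Isl2 (-0.61) and Hoxa3 (-0.52), of Medag (-0.46), Jade2 (-0.45), Tmie (-0.43), Frat1 (-0.43) and Zdhhc24 (-0.42). Adjusted p of these genes without a printed value ranged from 0.000432 for Jade2 to 0.0412 for Isl2. With only the groups compared in the fit, Apol8, Olfr635, Cln3, Isl2, Hoxa3, Medag, Tmie and Frat1 no longer passed, at adjusted p of 0.0504 to 0.106. Isl2 also did not pass with no filter (0.0711) or with the authors' factors (0.0758), and Cln3 did not without stretched control replicate 5 (0.49, adjusted p = 0.0521).

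Of 32 immediate early genes, which need no new protein for their induction, 11 rose and none fell in control cells, and 21 did not pass. Adjusted over the list alone, 12 rose and 1 fell. Atf3 rose by 0.60 (SE 0.0774, adjusted p = 3.83e-05), Fosl2 by 0.35 (SE 0.0365, adjusted p = 1.28e-06), Egr4 by 0.56 (SE 0.167, adjusted p = 0.0431) and Myc by 0.32 (SE 0.085, adjusted p = 0.0253). Well-known members did not pass, among them Fos (-0.36, SE 0.213), Egr1 (-0.65, SE 0.241) and Fosb (0.17, SE 0.211). Egr4, Myc, Fos, Egr1 and Fosb were singled out here after their values were seen. Fosb varied from 3.57 to 9.59 CPM between non-stretched control libraries, so a small rise could be missed. The list passed camera (adjusted p = 1.92e-07, adjusted p = 0.355 with an estimated correlation). Of 15 MAP kinase feedback regulators, 4 rose and none fell, and adjusted over the list alone 5 rose and 2 fell (camera adjusted p = 0.0316, adjusted p = 0.355 with an estimated correlation). Dusp8 and Dusp10 (0.24, SE 0.0503, adjusted p = 0.00474) were among them. Without stretched control replicate 5, this list did not pass (adjusted p = 0.115).

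Some genes of the contractile and cytoskeletal programme rose in the same comparison, while most members of these lists did not pass. Of 22 targets of the actin-regulated factors SRF and MRTF, 6 rose and none fell, or 12 and none adjusted over the list alone. Srf itself rose by 0.37 (SE 0.0447, adjusted p = 7.27e-06) and its cofactor gene Fhl2 by 0.35 (SE 0.0446, adjusted p = 2e-05). The list passed camera (adjusted p = 3.53e-08, adjusted p = 0.0858 with an estimated correlation), and without stretched control replicate 5 the number that rose was 13. Actc1, the cardiac alpha-actin, rose by 0.48 (SE 0.068, adjusted p = 0.000117) and Tpm1, a tropomyosin, by 0.14 (SE 0.0339, adjusted p = 0.0124). They were the 2 of 26 sarcomere genes that rose, also adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.356 with an estimated correlation), and 4 rose without stretched control replicate 5. Among 15 hypertrophy and stretch markers, Ankrd1 and the growth factor Gdf15 (0.25, SE 0.0557, adjusted p = 0.00814) rose and none fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.00886, adjusted p = 0.356 with an estimated correlation). Of 19 targets of the stretch-sensitive factors YAP and TEAD, 4 rose and none fell, or 4 and 1 adjusted over the list alone, with Ankrd1 and F3 (0.21, SE 0.0435) leading. That list passed camera (adjusted p = 0.0304, adjusted p = 0.593 with an estimated correlation) but not without stretched control replicate 5 (adjusted p = 0.184).

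In further lists that passed camera a minority of members passed. Of 24 integrated stress response genes, 4 rose and none fell, with the same numbers over the list alone, led by Atf4, its central transcription factor (0.22, SE 0.025, adjusted p = 4.71e-06), and Sesn2 (0.34, SE 0.0588). The list passed camera (adjusted p = 3.51e-05, adjusted p = 0.355 with an estimated correlation). Of 34 genes of the G2/M phase of the cell cycle, 5 fell and none rose, or 8 fell adjusted over the list alone, including the mitotic kinase Plk1 (-0.18, SE 0.0306, adjusted p = 0.000654) and Dlgap5 (-0.14, SE 0.0324). Camera gave an adjusted p = 0.000149, and adjusted p = 0.607 with an estimated correlation. Of 27 glycolysis genes, 5 fell and none rose, or 6 fell adjusted over the list alone, including the lactate transporter Slc16a3 (-0.16, SE 0.0322) and hexokinase Hk1 (-0.14, SE 0.0276). The glycolysis list passed camera (adjusted p = 0.00211, adjusted p = 0.355 with an estimated correlation). With only the groups compared in the fit, Dlgap5 (0.0687) and Slc16a3 (0.0679) did not pass, nor did Hk1 with GC content and length removed (0.0659).

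Several lists had members moving both ways or did not pass camera. Among 19 circadian clock genes 1 rose and 4 fell, including Nr1d1 (-0.28, SE 0.0411) and Per3 (-0.27, SE 0.064), and adjusted over the list alone 2 rose and 4 fell. Among 24 targets of NF-kB 1 rose and 3 fell (1 and 5 over the list alone, and 1 and 6 without stretched control replicate 5), including Nfkbie (-0.37, SE 0.0486) and Nfkb2 (-0.14, SE 0.0367). Among 18 muscle atrophy ubiquitin ligases 3 rose and 3 fell, with the same numbers over the list alone. Fbxl22 (0.32, SE 0.0625) and Asb2 (0.21, SE 0.0517) rose, as did Trim63. Nfkb2 did not pass with only the groups compared in the fit (0.0897), with the authors' factors (0.0716), with no filter (0.0513) or with GC content and length removed (0.056). Only 4 of 15 fixed macrophage markers were measured. Cd68 rose from 1.39 to 2.21 CPM (adjusted p = 0.00349) and Itgam from 0.133 to 0.296 CPM (adjusted p = 0.0305), which are low levels (camera adjusted p = 0.00211, adjusted p = 0.0858 with an estimated correlation).

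The number of calls in control cells depended on single libraries and on the test, with 2887 in limma-voom and 377 with only the groups compared in the fit. It was 2023 without stretched control replicate 5, of which 822 rose and 1201 fell, with 831 genes called both ways, and it was 568 without stretched control replicate 1. Without stretched control replicate 5, 6 more lists passed camera with the preset correlation, and few of their members passed. Proteasome subunits (adjusted p = 9.84e-05, 5 of 31 rose), NRF2 targets (0.023, 5 of 24 rose and 1 fell), interferon-stimulated genes (0.025, 2 of 42 rose), ribosomal protein genes (0.00445, 1 of 44 rose) and mitochondrially encoded transcripts (0.013, 0 of 13 rose) shifted upwards. Matrix genes (0.023, 8 of 32 fell and 1 rose) shifted downwards. The estimated correlation was not applied without that library, and with all libraries none of the 6 passed either way. The share of calls that rose was 42.9%. It was 60.7% with no filter, 57.0% with the stricter filter, 58.9% with only the groups compared in the fit and 60.2% with GC content and length removed. Lower shares included 35.8% without the 2 outlying libraries, 41.2% with the code letter as a block and 41.4% with limma-voom.

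**Figure D2:**
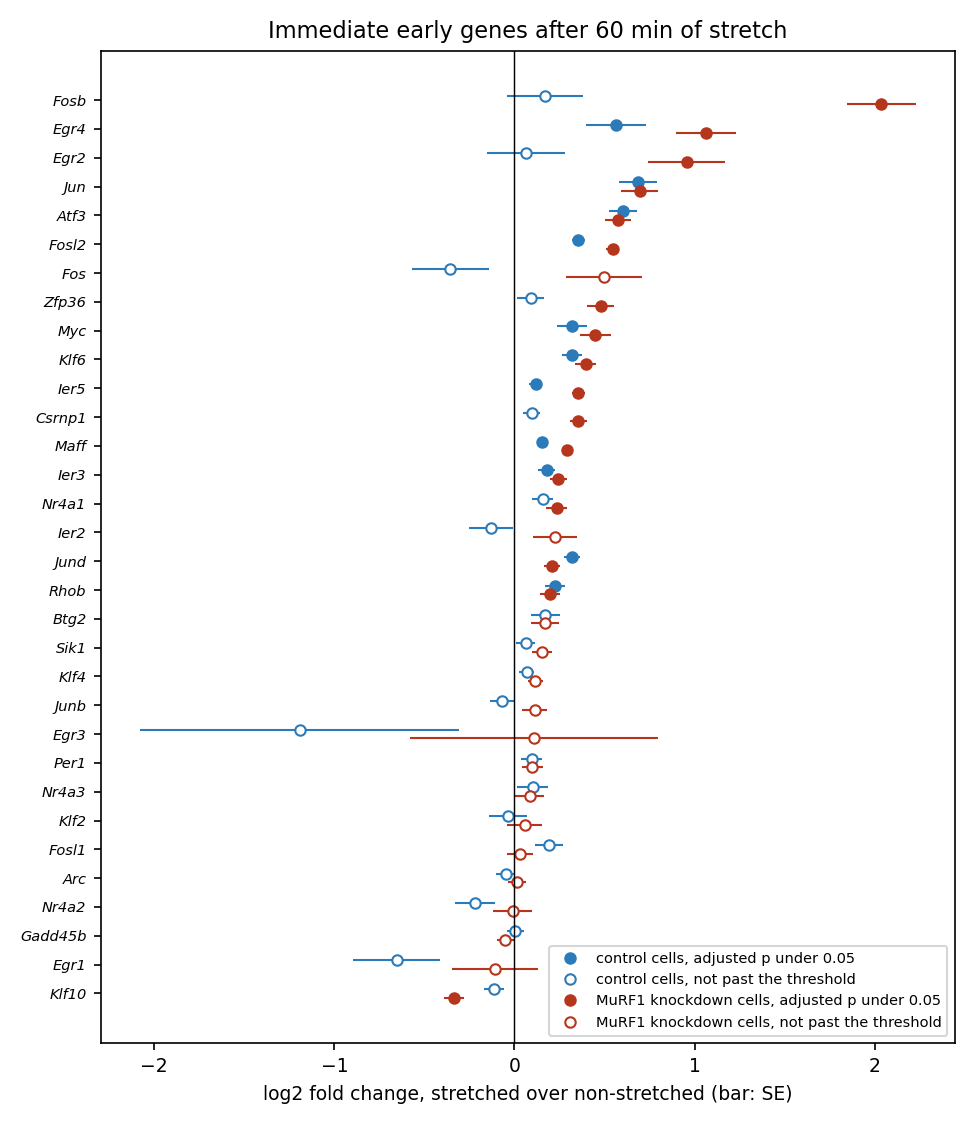
Log2 fold change with stretch (horizontal axis) of each tested gene of the immediate early list, in control and in MuRF1 knockdown cells. Points are estimates, bars are the SE, and filled points had an adjusted p under 0.05 in edgeR's test. Jun rose in both kinds of cell. Fosb rose by 2.04 in knockdown cells, and stood at 0.17 in control cells, not past the threshold.

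In knockdown cells, stretch raised the AP-1 subunit Fosb from 7.07 ± 1.38 to 29.0 ± 6.13 CPM (SD, n = 6 each), a log2 fold change of 2.04 (SE 0.191, adjusted p = 2.95e-07). Thbs1, which encodes the matrix protein thrombospondin-1, rose from 35.2 ± 3.50 to 74.3 ± 5.44 CPM (SD, n = 6 each, adjusted p = 4.81e-08). It was also higher with stretch in control cells, at 83.2 ± 6.83 against 53.8 ± 9.36 CPM (SD, n = 6 each). Jun, repeated here from the control cells, rose by 0.69 (SE 0.103, adjusted p = 0.000103), Dusp8 by 0.60 (SE 0.0563, adjusted p = 1.31e-07) and Actc1 by 0.73 (SE 0.0712, adjusted p = 2.15e-07). Txnip fell from 210 ± 10.1 to 138 ± 10.3 CPM (SD, n = 6 each, adjusted p = 1.91e-07), and its paralogue Arrdc4 fell by 0.46 (SE 0.0559, adjusted p = 3.86e-06).

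A total of 1287 genes passed in knockdown cells, 767 rising and 520 falling, with a median absolute log2 fold change of 0.189. The excess of rises was lost without the 2 outlying libraries, where 1104 of 2216 calls rose and 1112 fell. More than 2-fold, 42 rose and 2 fell. Further large rises were those of Apol8 (1.39, SE 0.205, adjusted p = 6.34e-05), Cldn15 (1.06, SE 0.125, adjusted p = 2.57e-06), Rnf225 (0.96), the early growth response factor Egr2 (0.96, SE 0.215, adjusted p = 0.00547), the sialomucin Cd34 (0.79) and Fbxl22 (0.76), an F-box protein of the sarcomere. Further large falls were those of Khnyn (-0.64, SE 0.199), Isl2 (-0.58, SE 0.179), Wnt9a (-0.50, SE 0.0667) and the zinc finger genes Zfp759 (-0.47) and Zfp953 (-0.45). Znrd1as (-0.45) is antisense to its neighbour and uncertain. Khnyn and Isl2 lost their calls with no filter (adjusted p = 0.0652 and 0.0577), with only the groups compared in the fit (0.0641 and 0.0598) and with the authors' factors (0.0529 and 0.0556).

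Of 32 immediate early genes, 16 rose and 1 fell in knockdown cells, or 19 and 1 adjusted over the list alone. Fosl2 rose by 0.54 (SE 0.0372, adjusted p = 5.18e-10) and Ier5 by 0.35 (SE 0.0353, adjusted p = 2.1e-07); Klf10, chosen after its value was seen, fell by 0.33 (SE 0.0552, adjusted p = 0.000204). The list passed camera (adjusted p = 1.99e-14, adjusted p = 0.106 with an estimated correlation). Of 15 MAP kinase feedback regulators 6 rose and none fell, or 6 and 1 adjusted over the list alone, with Dusp5 up by 0.63 (SE 0.0831; list in camera, adjusted p = 0.00364, adjusted p = 0.114 with an estimated correlation). Among SRF and MRTF targets 8 of 22 rose and none fell, or 14 adjusted over the list alone (camera adjusted p = 5.08e-10, adjusted p = 0.0893 with an estimated correlation). With stretched control replicate 5 left out, 14 of them rose. Srf rose by 0.37 (SE 0.0449) and Fhl2 by 0.38 (SE 0.0463), close to their changes in control cells. Of 19 YAP and TEAD targets 5 rose and none fell, or 6 adjusted over the list alone, including Amotl2 (0.27, SE 0.0397) and Ankrd1 (0.38, SE 0.0669). That list also passed camera (adjusted p = 0.027, adjusted p = 0.325 with an estimated correlation).

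Some heart muscle genes rose with stretch in knockdown cells, while most members of these lists did not pass. Among 26 sarcomere genes 4 rose and none fell, or 6 adjusted over the list alone, including Actc1 and the titin cap gene Tcap (0.71, SE 0.206; list in camera, adjusted p = 5.04e-05, adjusted p = 0.106 with an estimated correlation). In a fit without stretched control replicate 5, 10 rose. Of 26 calcium handling and ion channel genes 7 rose and none fell, or 10 over the list alone. The L-type calcium channel Cacna1c (0.23, SE 0.0531) was among them (camera adjusted p = 0.000371, adjusted p = 0.113 with an estimated correlation). Of 14 cardiac transcription factors 4 rose and none fell, or 5 over the list alone, with Gata6 (0.21, SE 0.0343) and Myocd (0.15, SE 0.0349) leading (camera adjusted p = 0.000371, adjusted p = 0.101 with an estimated correlation). Myocd lost its call with the authors' factors (adjusted p = 0.246). Of 15 hypertrophy and stretch markers 4 rose and none fell, or 4 and 1 over the list alone, including Rcan1 (0.10, SE 0.0255; list in camera, adjusted p = 0.0259, adjusted p = 0.289 with an estimated correlation).

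Stress and metabolic lists also passed camera in knockdown cells. Of 22 heat shock genes 6 rose and none fell, or 7 over the list alone, including Dnajb4 (0.47, SE 0.0548) and Bag3 (0.24, SE 0.0333; list in camera, adjusted p = 0.000979, adjusted p = 0.312 with an estimated correlation). Of 20 unfolded protein response genes of the endoplasmic reticulum 5 fell and none rose, or 9 fell over the list alone, including Sdf2l1 (-0.25, SE 0.0367) and Creld2 (-0.16, SE 0.0391; list in camera, adjusted p = 5.04e-05, adjusted p = 0.253 with an estimated correlation). Of 27 cholesterol synthesis genes 6 rose and none fell, or 8 over the list alone, with Hsd17b7 up by 0.34 (SE 0.0465; list in camera, adjusted p = 1.38e-06, adjusted p = 0.253 with an estimated correlation). Of 38 genes of G1/S and DNA replication 6 rose and none fell, or 8 over the list alone, including Dtl (0.12, SE 0.0258; list in camera, adjusted p = 0.00109, adjusted p = 0.312 with an estimated correlation). The kinase gene Sgk1, in the insulin and FoxO list, rose by 0.73 (SE 0.0892, adjusted p = 4.26e-06). That list had 5 rises and 2 falls among 26, also over the list alone, and did not pass camera (adjusted p = 0.0753). The integrated stress response list, with 2 rises and 3 falls among 24 (2 and 5 over the list alone), did not pass either (adjusted p = 0.0705), while Ddit3 fell by 0.29 (SE 0.0559). When stretched control replicate 5 was left out, 7 of that list fell (adjusted p = 0.0545).

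Matrix and signalling lists moved upwards in few members. Of 32 matrix and adhesion genes 4 rose and none fell, also over the list alone, with Thbs1 leading (camera adjusted p = 0.00111, adjusted p = 0.253 with an estimated correlation). Of 22 TGF-beta targets 4 rose and none fell, or 5 and 1 over the list alone, including Ctgf (0.39, SE 0.0963; list in camera, adjusted p = 0.0311, adjusted p = 0.194 with an estimated correlation). Another 4 lists passed camera with few calls. These were muscle atrophy ligases with 4 rises among 18 (adjusted p = 0.0347, adjusted p = 0.194 with an estimated correlation), NRF2 targets with 3 among 24 (0.0314, adjusted p = 0.493 with an estimated correlation), thyroid hormone response with 4 rises and 1 fall among 17 (0.035, adjusted p = 0.253 with an estimated correlation), and interferon-stimulated genes with 1 fall among 42 (0.00182, adjusted p = 0.634 with an estimated correlation). Adjusted over the list alone, their rises and falls were 4 and 0, 5 and 0, 5 and 1, and 0 and 0. Ribosomal protein genes shifted downwards as a set with none of 44 called, over all genes or over the list alone (camera adjusted p = 0.045, adjusted p = 0.792 with an estimated correlation). With stretched control replicate 5 left out, 5 NRF2 targets rose, 3 ribosomal protein genes fell, and oxidative phosphorylation genes passed as well, downwards (adjusted p = 0.0294 against 0.13).

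Markers of other cell types were measured in the same fit. Of 11 fibroblast markers, Vim rose by 0.11 (SE 0.0328, adjusted p = 0.0365) and none fell, also over the list alone (camera adjusted p = 0.027, adjusted p = 0.194 with an estimated correlation). Vim did not pass with no filter (adjusted p = 0.0597). Of 9 smooth muscle markers 2 rose and none fell, or 4 over the list alone, and they were Myocd and Lmod1 (0.37, SE 0.0902; list in camera, adjusted p = 0.00421, adjusted p = 0.116 with an estimated correlation). In a fit without stretched control replicate 5 the knockdown comparison had 1930 calls, and 1287 genes were called both ways; 2 fibroblast and 4 smooth muscle markers then rose. It had 856 without stretched knockdown replicate 4.

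Knockdown of MuRF1 without stretch changed more than every second gene that was tested. Among genes that the naming rule covers, the rises were led by Zscan4f, a zinc finger gene of the early embryo. It stood at 18.5 ± 1.79 against 3.80 ± 0.630 CPM (SD, n = 6 each, log2 fold change 2.27, SE 0.113, adjusted p = 1.85e-15). Some genes of low count rose more, such as Usp17lc (3.05). The falls beside Trim63 included Angpt1, which encodes the vessel growth factor angiopoietin-1, at 6.69 ± 0.396 against 35.9 ± 5.20 CPM (SD, n = 6 each, adjusted p = 6.96e-18). Ryr2, the calcium release channel of the cardiac sarcoplasmic reticulum, stood at 125 ± 8.07 against 270 ± 6.93 CPM (SD, n = 6 each, adjusted p = 2.83e-19). Hmgcs1, an early enzyme of cholesterol synthesis, stood at 210 ± 4.59 against 454 ± 34.0 CPM (SD, n = 6 each, adjusted p = 1.41e-16), and was chosen after its value was seen. Xbp1, a transcription factor of the unfolded protein response, rose to 115 ± 4.65 from 64.3 ± 1.58 CPM (SD, n = 6 each, adjusted p = 4.68e-18).

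In edgeR's test 8325 genes passed, 57.8% of those tested, with 4040 higher and 4285 lower in knockdown cells. The balance turned in other settings, to 5337 higher and 3930 lower with GC content and length removed and to 4881 and 3691 with no filter. The median absolute log2 fold change of these genes was 0.307, and 364 rose and 448 fell more than 2-fold. Further large rises were those of Stox1 (2.21), Zscan4d (2.14), Shisa8 (2.14, SE 0.0931, adjusted p = 5.87e-17), Usp17le (2.10), Zscan4b (2.06), Zscan4e (2.05) and Derl3 (2.01), a gene of protein degradation at the endoplasmic reticulum. Zscan4 and Usp17 genes are near-identical families, so their single values are uncertain. Further large falls were those of Hsd3b1 (-2.87), Otof (-2.73), Scrg1 (-2.68, SE 0.129, adjusted p = 1.1e-15), Chl1 (-2.61), Ceacam20 (-2.40) and Adamtsl2 (-2.39). When stretched control replicate 5 was left out, 8888 genes passed, and 8323 were called both ways. TMM scaling takes most genes as unchanged, so a shift shared by most genes would not be seen. Its factors were 1.02 to 1.06 in knockdown libraries and 0.937 to 0.973 in control libraries, except 1.04 in stretched control replicate 5. The direction of small changes can thus depend on the scaling.

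Genes of cholesterol synthesis and its regulator SREBP fell without exception, 27 of 27, also over the list alone, with a median log2 fold change of -0.86 (camera adjusted p = 9.7e-18, adjusted p = 0.035 with an estimated correlation). Hsd17b7 stood at 72.5 ± 3.65 against 173 ± 10.5 CPM (SD, n = 6 each). Of 27 glycolysis genes 25 fell and none rose, also over the list alone, including Hk1 (-0.73, SE 0.0278) and Pdk4 (-1.06, SE 0.0451; list in camera, adjusted p = 2.16e-12, adjusted p = 0.00555 with an estimated correlation). Of 29 PPAR-alpha targets and fatty acid oxidation genes 21 fell and 2 rose (21 and 3 over the list alone), including Cpt1a, which carries fatty acids towards the mitochondrion (-0.95, SE 0.0288; list in camera, adjusted p = 2.6e-05, adjusted p = 0.0278 with an estimated correlation). Of 25 hypoxia response genes 16 fell and 2 rose (17 and 2 over the list alone), including Slc2a1, a glucose transporter (-0.96, SE 0.0482; list in camera, adjusted p = 0.000416, adjusted p = 0.0248 with an estimated correlation). Of 48 nuclear-encoded oxidative phosphorylation genes 39 fell and 1 rose (39 and 2 over the list alone), including Atp5b (-0.49, SE 0.0301; list in camera, adjusted p = 1.97e-07, adjusted p = 0.431 with an estimated correlation).

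Genes of the heart muscle cell were lower. Of 26 sarcomere genes 21 fell and 2 rose, also over the list alone, including the troponin I genes Tnni1 (-1.61, SE 0.0558) and Tnni3 (-1.67, SE 0.0697; list in camera, adjusted p = 1.11e-08, adjusted p = 0.0136 with an estimated correlation). Of 26 calcium handling and ion channel genes 23 fell and 1 rose (24 and 1 over the list alone), including Ryr2 (-1.11, SE 0.0377; list in camera, adjusted p = 1.61e-10, adjusted p = 0.00555 with an estimated correlation). Of 14 cardiac transcription factors 10 fell and 4 rose, also over the list alone, with Myocd (-0.83, SE 0.0346) and Hand2 (-0.60, SE 0.033) among the falls (camera adjusted p = 0.00589, adjusted p = 0.0764 with an estimated correlation). The rises were those of Tbx2, Tbx3, Nkx2-5 and Prox1, named after their values were seen; Tbx2 and Tbx3 are known as repressors of the working myocardial programme. SRF and MRTF targets fell with the knockdown in 18 of 22 cases, with 1 rise, also over the list alone. Myl9 (-1.04, SE 0.0456) and Cnn2 (-0.70, SE 0.0258) led them (camera adjusted p = 1.97e-07, adjusted p = 0.0372 with an estimated correlation). Of 18 muscle atrophy ligases 10 fell and 3 rose, also over the list alone, and Trim63 itself is a member (camera adjusted p = 0.0124, adjusted p = 0.0764 with an estimated correlation).

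Genes of the extracellular matrix were lower as well. Of 32 matrix and adhesion genes 26 fell and 1 rose (27 and 1 over the list alone), including the collagen gene Col5a2 (-1.21, SE 0.0309) and N-cadherin, Cdh2 (-1.03, SE 0.0271; list in camera, adjusted p = 2.53e-11, adjusted p = 0.02 with an estimated correlation). Of 11 fibroblast markers 10 fell and none rose, also over the list alone. Col1a1 fell by 1.40 (SE 0.0419) and Col3a1 by 1.71 (SE 0.0558; list in camera, adjusted p = 6.58e-07, adjusted p = 0.00555 with an estimated correlation). Of 9 smooth muscle markers 7 fell and none rose, also over the list alone, including Mylk (-0.98, SE 0.0444; list in camera, adjusted p = 0.000985, adjusted p = 0.0409 with an estimated correlation). Among 6 endothelial markers 2 fell, among 7 skeletal muscle markers 5 fell and 1 rose, and among 4 macrophage markers 2 rose, with the same numbers over each list alone. These 3 lists did not pass camera (adjusted p = 0.384, 0.238 and 0.306). Of 22 TGF-beta targets 14 fell and 3 rose, also over the list alone, including Itgb5 (-0.70, SE 0.031; list in camera, adjusted p = 0.012, adjusted p = 0.0799 with an estimated correlation).

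Stress lists moved in different directions in knockdown cells. All 20 measured genes of the unfolded protein response rose, also over the list alone, including Xbp1 and Sdf2l1 (0.95, SE 0.0375; list in camera, adjusted p = 1.32e-13, adjusted p = 0.0354 with an estimated correlation). Of 42 interferon-stimulated genes 36 rose and 1 fell, also over the list alone, including the chemokine Cxcl10 (1.41, SE 0.117) and the guanylate-binding protein gene Gbp2 (0.78, SE 0.0752; list in camera, adjusted p = 5.56e-09, adjusted p = 0.334 with an estimated correlation). Of 26 p53 targets 16 rose and 5 fell, also over the list alone, with the cell cycle inhibitor Cdkn1a up by 0.82 (SE 0.0314; list in camera, adjusted p = 0.000795, adjusted p = 0.051 with an estimated correlation). Perp fell by 3.21 (SE 0.49), named after its value was seen. Of 24 integrated stress response genes 15 rose and 3 fell, also over the list alone, including Sesn2 (0.78, SE 0.0583; list in camera, adjusted p = 0.00139, adjusted p = 0.238 with an estimated correlation). Of 22 heat shock genes 16 fell and 2 rose, also over the list alone, including Cryab (-1.12, SE 0.0565) and Hspb6 (-0.66, SE 0.0341; list in camera, adjusted p = 0.00062, adjusted p = 0.334 with an estimated correlation). Of 34 G2/M genes 23 fell and 1 rose (24 and 1 over the list alone), including Kif20a (-0.28, SE 0.0221; list in camera, adjusted p = 5.69e-05, adjusted p = 0.336 with an estimated correlation).

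Other lists moved both ways. Of 17 thyroid hormone response genes 12 fell and 4 rose, also over the list alone, including Dio2, which activates thyroid hormone (-1.98, SE 0.0557; list in camera, adjusted p = 0.00115, adjusted p = 0.061 with an estimated correlation). Of 26 insulin and FoxO genes 16 fell and 5 rose (16 and 6 over the list alone), including Igfbp5 (-1.72, SE 0.0591; list in camera, adjusted p = 0.00593, adjusted p = 0.0799 with an estimated correlation). Of 24 NRF2 targets 14 fell and 4 rose, also over the list alone, including Gstm1 (-0.94, SE 0.0593; list in camera, adjusted p = 0.00974, adjusted p = 0.412 with an estimated correlation). Immediate early genes did not pass as a list (11 rises and 5 falls among 32, also over the list alone; list in camera, adjusted p = 0.101), although Arc rose by 0.94 (SE 0.0496) and Jund by 0.74 (SE 0.045). The YAP target Amotl2 rose by 1.16 (SE 0.0407), while its list had 9 rises and 5 falls among 19 (9 and 7 over the list alone) and did not pass (camera adjusted p = 0.197). Proteasome subunits, with 8 rises and 2 falls among 31, did not pass either (camera adjusted p = 0.164), with the same numbers over the list alone. Ribosomal protein genes had 13 falls and 1 rise among 44, also over the list alone, and did not pass (camera adjusted p = 0.116). With stretched control replicate 5 left out they did (adjusted p = 0.00146), with 27 falls and 2 rises.

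**Figure D3:**
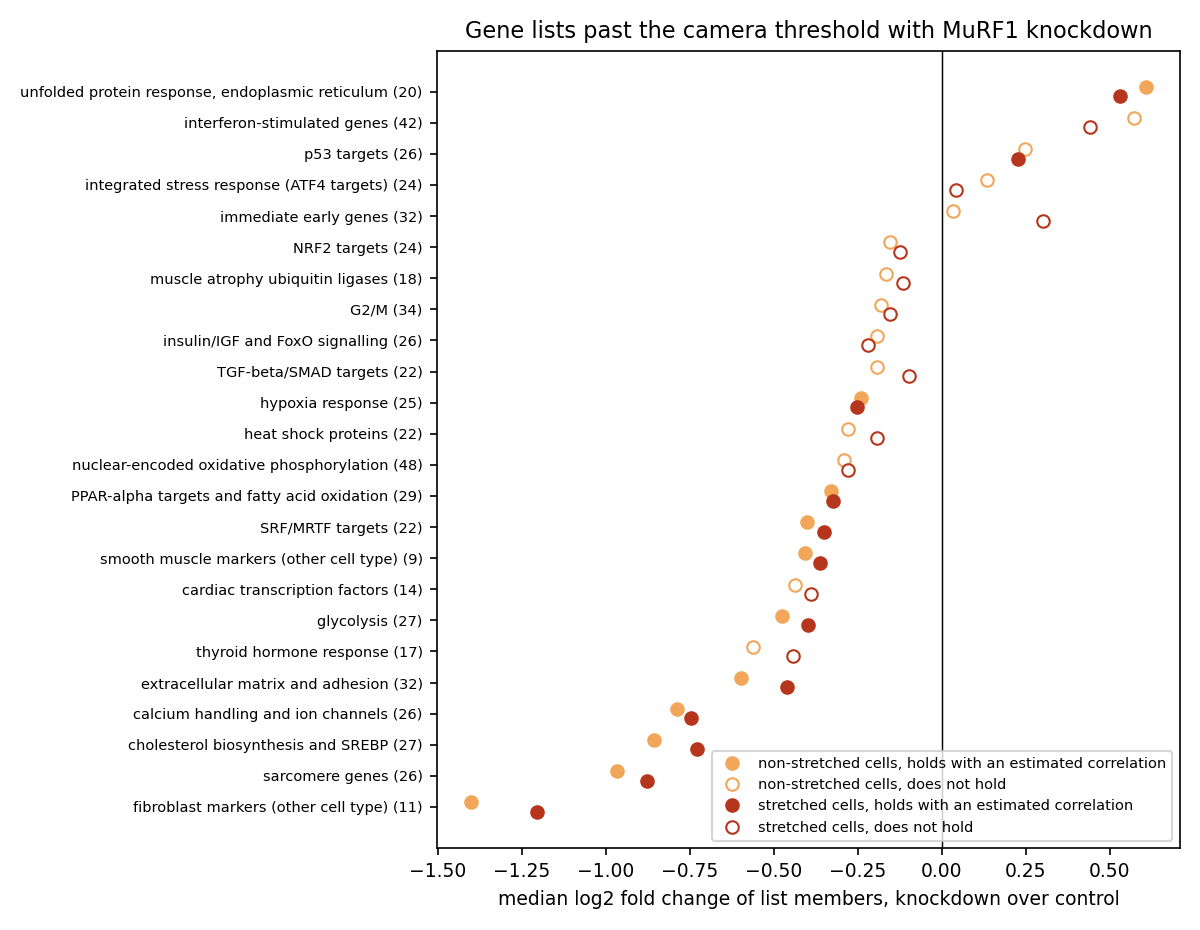
Median log2 fold change by MuRF1 knockdown (horizontal axis) of the members of each fixed list that passed camera without or with stretch. Filled points passed with an estimated correlation, and open points did not. Cholesterol synthesis genes lay at -0.86 and -0.73 and unfolded protein response genes at 0.61 and 0.53, on opposite sides of 0.

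Knockdown in stretched cells gave much the same picture. Zscan4f stood at 17.9 ± 2.77 against 3.73 ± 0.647 CPM (SD, n = 6 each; log2 fold change 2.24, SE 0.114, adjusted p = 4.76e-15), and Fosb at 29.0 ± 6.13 against 7.06 ± 1.10 CPM (SD, n = 6 each; log2 fold change 2.05, SE 0.193, adjusted p = 4.21e-09). Ryr2 fell by 0.96 (SE 0.0376) and the sarcomere gene Ldb3 by 1.09 (SE 0.0534). Atf3 rose by 1.23 (SE 0.075, adjusted p = 3.75e-13) and Hyou1, a chaperone of the endoplasmic reticulum, by 0.83 (SE 0.037, adjusted p = 1.45e-16).

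Here 7494 genes passed, 52.0% of those tested, with 3619 higher and 3875 lower, and with 310 rises and 349 falls over 2-fold. With GC content and length removed 4837 were higher and 3724 lower, and with no filter 4012 and 3499. Under the naming rule, the largest rises also included Zscan4e (2.20), Usp17le (2.18), Zscan4b (2.12), Zscan4c (2.06), Zscan4d (2.01) and Lhfpl2 (1.97). Besides Trim63, the largest falls under that rule were those of Hsd3b1 (-2.46), Scrg1 (-2.26), Ceacam20 (-2.22), Aldh1a7 (-2.16), Adamtsl2 (-2.12), the mast cell chymase gene Cma1 (-2.12) and Chl1 (-2.09). In a fit without stretched control replicate 5, 8017 genes passed, and 7083 were called both ways.

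All 27 cholesterol synthesis genes fell again (camera adjusted p = 1.51e-18, adjusted p = 0.0267 with an estimated correlation), and 18 of 20 unfolded protein response genes rose (4.07e-13, adjusted p = 0.0357 with an estimated correlation). Glycolysis genes fell in 25 of 27 cases (1.12e-12, adjusted p = 0.00679 with an estimated correlation), sarcomere genes in 22 of 26 with 2 rises (5.96e-10, adjusted p = 0.00679 with an estimated correlation) and calcium handling genes in 23 of 26 with 1 rise (3.29e-11, adjusted p = 0.00587 with an estimated correlation). Matrix genes fell in 25 of 32 cases with 1 rise (7.04e-11, adjusted p = 0.0204 with an estimated correlation), fibroblast markers in 10 of 11 (1.82e-06, adjusted p = 0.00679 with an estimated correlation) and SRF targets in 19 of 22 (1.52e-08, adjusted p = 0.0265 with an estimated correlation). Adjusted over the list alone these numbers were the same, except 26 falls in glycolysis. Smooth muscle markers fell in 7 of 9 cases with 1 rise (0.000888, adjusted p = 0.0357 with an estimated correlation), and p53 targets rose in 18 of 26 with 5 falls (0.000322, adjusted p = 0.0357 with an estimated correlation), with the same numbers over each list alone. Fatty acid oxidation genes fell in 20 of 29 cases with 4 rises (1.47e-05, adjusted p = 0.023 with an estimated correlation) and hypoxia genes in 15 of 25 with 2 rises (0.000235, adjusted p = 0.0204 with an estimated correlation), or 20 and 4, and 17 and 2, over the list alone.

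Some calls rested on the preset correlation. Interferon-stimulated genes rose in 32 of 42 cases with 1 fall (camera adjusted p = 2.3e-07, adjusted p = 0.403 with an estimated correlation), with Cxcl10 up by 1.08 (SE 0.118). Oxidative phosphorylation genes fell in 38 of 48 cases (2e-08, adjusted p = 0.403 with an estimated correlation), and G2/M genes in 22 of 34 with 1 rise (0.00046, adjusted p = 0.403 with an estimated correlation). Immediate early genes passed in this comparison, with 16 rises and 3 falls among 32 (0.000473, adjusted p = 0.403 with an estimated correlation). Over the list alone these 4 had 32 and 1, 0 and 39, 1 and 22, and 16 and 3. The integrated stress response list did not pass (adjusted p = 0.179), with 8 rises and 3 falls among 24, also over the list alone. Ribosomal protein genes did not pass with 15 falls and 1 rise among 44 (14 and 1 over the list alone; list in camera, adjusted p = 0.084), but did so without stretched control replicate 5, the library low in these transcripts (adjusted p = 1.55e-08, with 39 falls and 1 rise). Mitochondrially encoded transcripts also passed camera without it, with 8 of 13 lower (adjusted p = 0.0392 against 0.662). Neither call was checked with an estimated correlation, which was not applied without that library.

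The response to stretch differed between knockdown and control cells for 3 genes in the interaction test. The same term is the difference between the knockdown effects with and without stretch, which were smaller with stretch on the whole. The slope was 0.820, and 0.896 when error in the effects without stretch was allowed for. Without stretch the knockdown effect was -1.88 for Pdzd2, -2.07 for Dkk3 and 0.18 for Fosb. The terms of Pdzd2 and Dkk3 thus cannot be told apart from that general shrinkage, which would not make the term of Fosb positive. An average slope does not settle single genes either way, and Trim63 lay at -3.52 without and -3.51 with stretch. Fosb rose with stretch in knockdown cells and not detectably in control cells, an interaction of 1.87 (SE 0.284, adjusted p = 0.0181). Non-stretched control libraries varied in Fosb, from 3.57 to 9.59 CPM, and in Jun, from 46.1 to 72.6 CPM. Replicates 1, 4 and 6 of that group were highest in both, so a small rise of Fosb in control cells could be missed. Pdzd2, which encodes a scaffold protein with PDZ domains, stood at 234 ± 5.23 and 222 ± 18.6 CPM in non-stretched and stretched control cells, and at 63.4 ± 4.51 and 78.6 ± 3.07 CPM in the knockdown groups (SD, n = 6 each; interaction 0.38, SE 0.0652, adjusted p = 0.0222). Dkk3, a secreted protein of the Dickkopf family, stood at 447 ± 13.3 and 434 ± 18.8 CPM, and at 106 ± 5.59 and 128 ± 7.97 CPM, in the same order (SD, n = 6 each; interaction 0.31, SE 0.0555, adjusted p = 0.0301). Fosb lies on chromosome 7 at 19302696 to 19310051, Pdzd2 on chromosome 15 at 12359711 to 12739924 and Dkk3 on chromosome 7 at 112116017 to 112159057, all on the minus strand of GRCm38.

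**Figure D4:**
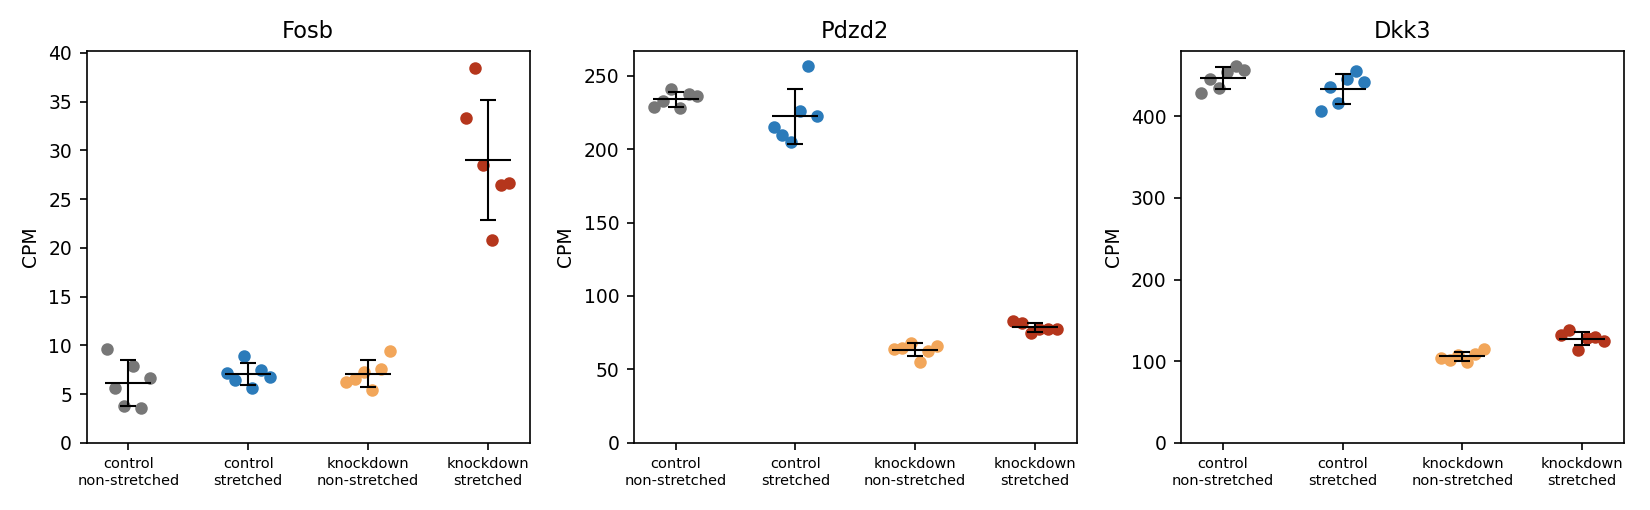
Fosb, Pdzd2 and Dkk3 in CPM (vertical axes) for each library, by group; points are libraries and bars are the mean with the SD of 6. All 3 were higher with stretch in knockdown cells, while Pdzd2 at 234 and 222 CPM and Dkk3 at 447 and 434 CPM lay close together in control cells.

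These calls were not firm. Pdzd2 and Dkk3 did not pass with the authors' factors (adjusted p = 0.102 and 0.0509), nor did Dkk3 with no filter (0.0592). With each of the 24 libraries left out in turn, Fosb passed in 22 cases (highest adjusted p = 0.0548), Pdzd2 in 17 (highest 0.118) and Dkk3 in 12 (highest 0.135). Fosb did not pass without stretched control replicate 2 or non-stretched control replicate 6 (0.051). Pdzd2 was lost without these, stretched knockdown replicate 1 or 2, stretched control replicate 1 or 3, or non-stretched control replicate 5. Dkk3 was lost without any of those 7, or without stretched knockdown replicate 4 or 5, non-stretched knockdown replicate 2 or 4, or non-stretched control replicate 4. Unadjusted p was under 0.05 for 1355 genes, and 109 genes passed without stretched control replicate 5. Leaving out stretched control replicate 2 or non-stretched control replicate 6 left 0 calls, while 48 passed without non-stretched knockdown replicate 6. It was 1 gene without stretched knockdown replicate 1 or 2, stretched control replicate 1 or 3, or non-stretched control replicate 5. It was 5 without non-stretched knockdown replicate 5, 8 without non-stretched control replicate 2, 10 without stretched control replicate 4 and 17 without non-stretched knockdown replicate 1. The number was 126 with DESeq2, 205 with limma-voom, and 9 with the replicate number and 45 with the code letter as a block.

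Other named genes had interactions that did not pass with all libraries. Ier5 (0.24, SE 0.0502), Sgk1 (0.58, SE 0.123), Hk1 (0.18, SE 0.0392), Col1a1 (0.28, SE 0.0585) and Trib3 (-0.29, SE 0.0607) each had an adjusted p of 0.0619, and each passed without stretched control replicate 5 (0.0313, 0.0357, 0.0325, 0.00617 and 0.0264 in the same order). Egr2 (0.89, SE 0.304, adjusted p = 0.326) and Thbs1 (0.45, SE 0.124, adjusted p = 0.177) did not pass either, although both rose with stretch in knockdown cells. Thbs1 was also higher with stretch in control cells, at 83.2 against 53.8 CPM. Both genes were chosen after their values were seen. Of the 38 lists, 17 passed camera for the interaction and none did with an estimated correlation. The integrated stress response had the smallest camera adjusted p, at 1.43e-10 with a median of -0.12 and adjusted p = 0.0751 with an estimated correlation. Over all genes none of its 24 members passed, and adjusted over the list alone 7 were lower and none higher, while over all genes 5 were lower without stretched control replicate 5. Matrix genes (median 0.13, none of 32 past the threshold over all genes, 6 higher without that library, 8 higher over the list alone; list in camera, adjusted p = 3.43e-08, adjusted p = 0.0751 with an estimated correlation) and immediate early genes (median 0.09, Fosb alone over all genes, 2 higher without that library, 8 higher and 1 lower over the list alone; list in camera, adjusted p = 0.000473, adjusted p = 0.421 with an estimated correlation) also passed. The G2/M list did not pass without stretched control replicate 5 (adjusted p = 0.228). Oxidative phosphorylation (adjusted p = 0.000617), mitochondrially encoded (0.000689) and ribosomal protein transcripts (4.83e-11) then passed camera, all downwards. These calls used the preset correlation, as the estimated one was not applied without that library.

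Across 14411 genes, which are not independent replicates, the stretch responses of control and knockdown cells had a Pearson r of 0.33 and a Spearman rho of 0.41. They share no libraries. Of 388 genes called in both, 226 rose in both and 161 fell in both, against 19.6 and 17.6 for independent sets of calls. The stretch value of Pearson r was 0.0634 with no filter, 0.0982 with DESeq2, which was also run without a filter, and 0.427 with the stricter filter. The knockdown effects without and with stretch had a Pearson r of 0.87 and a Spearman rho of 0.85. Pearson r was 0.465 with no filter, 0.545 with DESeq2 and 0.943 with the stricter filter. Of 6630 genes called in both, 3065 rose in both and 3560 fell in both, against 1015 and 1152 for independent sets. Genes with little spread pass more easily in each comparison of the shared fit, so the numbers for independent sets are only a loose reference.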

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

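The test of independent culture plates and the removal of GC content and length as an alternative for the counts of genes were chosen only after the result was seen, while the share of fallen genes with the same 7-base match and the smooth on ribosomal protein genes were chosen after their patterns but before their own values were seen.

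Knockdown of MuRF1 changed 8325 of 14411 genes without stretch. Direct seed matches of one hairpin are argued against as the cause of all falls, since no 7-base match was carried by the 3' UTRs of more than 47.9% of the 4075 fallen genes searched, and a match would not directly raise the 4040 genes that rose. That share was of AAATAAA, expected in 49.4% by 3' UTR length. Rarer matches, such as CCCTGCC with 2931 carriers, could not reach all 4075 genes. The outcome was thus largely fixed beforehand and bears only on a single seed as the cause of all falls. Whether they caused part of the falls cannot be told apart: the leading match, CCCTGCC, had an excess of 4.39 percentage points over 13148 genes, and the bound of 10 points set in advance decides nothing, as planted seeds gave 5.77 to 10.3 points. Bias by GC content and transcript length is argued against as the source of the count, since 9267 genes passed after a smooth of both was removed, and independent differences between culture plates are hard to reconcile with effects that had a Pearson r of 0.874 without and with stretch. Other off-target effects, secondary effects and any batch shared by both knockdown groups stay open, as does a response to the loss of MuRF1, which the design names.

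Stretched control replicate 5 stood apart from its group in 4 measures: its mitochondrially encoded share was 1.45% against 2.95% to 3.26% in the other 5, its ribosomal protein share 3.27% against 4.54% to 4.76%, its replication-dependent histones 491 CPM against 222 to 244 CPM, and its second principal component 54.7 against -3.89 to 2.56. Weaker poly(A) selection cannot be told apart from other causes, because polyadenylated histone transcripts stood at 2734 CPM, against 2866 to 3571 CPM in the other 23 libraries, which decides nothing about transcripts without a tail. More cells in S phase would raise the G1/S list, whose median log2 deviation was -0.037, with 18 of 38 genes above the mean of the other 5. Removing the smooth of GC content and length, which explained 28.5% of the variance in this library and 27.5% in non-stretched knockdown replicate 4, 16.1% in non-stretched control replicate 1 and at most 11.0% elsewhere, left the histone excess at 2.53-fold, from 2.11-fold, and the median log2 deviation of 44 ribosomal protein genes at -0.339, from -0.625. That bias is thus argued against as the cause of the histone excess and as the whole cause of the low ribosomal protein transcripts. Whether it caused a part of the latter stays open. The smooth would take up a real fall of transcripts of like length and GC content in the same way. The bias also stays open for the other 2 measures, and the design names no biological cause for a single library.

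The effects of the knockdown were smaller in stretched than in non-stretched cells, with a slope of 0.820 (jackknife SE 0.0365) across 14411 genes. The outlying library argues poorly as the cause, since the slope was 0.831 without stretched control replicate 5. Regression dilution, by which error in the effects without stretch lowers the slope, explains part of it: the split-half slope was 0.896 (jackknife SE 0.0401), and its upper limit of 0.976 at 2 SE lies under 1. Stretch, the difference the design names, and any batch that goes with the group stay open.

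Another 6 values stood far from the other 5 of their group, where chance gives about 1 such group in 20 and 72 groups were examined. Stretched knockdown replicate 2 had 52.0 M counts against 38.2 to 43.0 M. Non-stretched knockdown replicate 4 had a mitochondrially encoded share of 3.67% against 2.51% to 2.81%. Stretched knockdown replicate 1 lay at 13.2 on the second principal component against 2.29 to 5.23, and its Trim63 level was 83.5 CPM against 59.9 to 67.9 CPM. Non-stretched knockdown replicate 6 had Jun at 112 CPM against 77.3 to 89.7 CPM and Thbs1 at 42.1 CPM against 32.9 to 35.0 CPM.

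The stretch response differed between knockdown and control cells for Fosb by 1.87, for Pdzd2 by 0.38 and for Dkk3 by 0.31 on the log2 scale, by the interaction term. The terms of Pdzd2 and Dkk3, which fell with the knockdown, cannot be told apart from the smaller knockdown effects with stretch described above. It also differed by camera for 17 lists, none of which passed with an estimated correlation. Their median interactions were 0.091 for immediate early genes, 0.092 for calcium handling and ion channels, 0.088 for cardiac transcription factors and 0.091 for heat shock proteins. They were 0.15 for fibroblast markers, 0.13 for matrix and adhesion, 0.11 for cholesterol synthesis, 0.081 for thyroid hormone response and 0.079 for insulin and FoxO signalling. Smaller medians were 0.073 for glycolysis, 0.075 for TGF-beta targets, 0.037 for G1/S and 0.033 for G2/M. Negative medians were -0.15 for interferon-stimulated genes, -0.12 for the integrated stress response, -0.060 for the unfolded protein response and -0.042 for proteasome subunits. Whether these list medians follow from the smaller knockdown effects with stretch was not tested.

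Splits of the same libraries into groups of the same sizes gave fewer genes than the real division in the 4 comparisons of 12 libraries. This argues only against a chance division of these libraries. A chance difference between cultures or batches that goes with the group would also put the real split first, so it is not excluded. Mixed splits also carry the group difference in their spread, which lowers their counts. For each result, 1 of 100 splits, the real one, gave as many genes, out of 462 possible splits for a comparison of 12 libraries and 213444 for the interaction. The real and the highest other counts were 857 and 18 for stretch in control cells, 1287 and 194 for stretch in knockdown cells, and 8325 and 4834 for the knockdown without stretch. They were 7494 and 3934 for the knockdown with stretch. For the interaction they were 3 and 2, and leaving out 1 library could leave 0 genes, so even a chance division of the libraries is not taken as excluded there.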

How the results depend on the processing

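Leaving out the 2 outlying libraries, the authors' factors as offsets, and the removal of GC content and length were chosen only after the data were seen. Both knockdown counts stayed within 1.5 times under all alternatives run, from 7974 to 8334 genes without stretch and from 7102 to 8017 with stretch when 1 library of the 2 groups compared was left out, and 8888 without stretch when stretched control replicate 5 was. Of 3480 values of named genes under alternatives, 3357 kept their direction and side of the threshold, 50 fell short of it, 70 newly passed and 3 reversed, none of them for a gene past the threshold. The 3 were the Trim63 interaction, at -0.0066 with no filter, -0.059 with limma-voom and -0.013 without the 2 outlying libraries. These totals do not include the fits with a single library left out. In those 24 fits the interaction passed 22 times for Fosb, 17 times for Pdzd2 and 12 times for Dkk3. Of the 320 named results, 82 and 84 were of the knockdown without and with stretch, so the totals say less about stretch and the interaction.

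Stretch in control cells gave 2887 genes with limma-voom, 377 with only the groups compared, 566 with the authors' factors, 1398 with GC content and length removed and 2933 without the 2 outlying libraries, and 568 to 2023 with 1 library of the 2 groups left out. Stretch in knockdown cells gave 2540 with limma-voom, 2120 with GC content and length removed and 2216 without the 2 outlying libraries, and 856 to 1259 with 1 library of the 2 groups left out, or 1930 without stretched control replicate 5. The interaction gave 126 genes with DESeq2, 205 with limma-voom, 9 with the replicate number and 45 with the code letter as a block, 1 with the authors' factors, 40 with GC content and length removed and 163 without the 2 outlying libraries, and 0 to 109 with 1 library left out. Same-numbered libraries of different groups had a median correlation of 0.015, and 8 of 24 correlated best with their own number, so the numbers were not used as pairs.

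The correlation of stretch effects was 0.0634 with no filter and 0.0982 with DESeq2, which was also run without a filter on low counts. It was 0.427 with the stricter filter, and 0.260 to 0.368 with 1 library left out. That of knockdown effects was 0.465 with no filter, 0.943 with the stricter filter and 0.545 with DESeq2, and 0.853 to 0.876 with 1 library left out. With an estimated correlation camera passed 0 lists in both stretch comparisons and in the interaction, 11 for the knockdown without stretch and 12 with stretch, and fry passed 11 for the interaction. The cause was not tested. What depth limits was not tested by varying it. At the real library sizes, 53.7% of simulated 1.2-fold changes were recovered for stretch in control cells.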

Other observations

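The tests on Zscan4 relatives, on the sequence shared by Trim63 and Trim55, and on zinc finger genes were conceived after those genes were seen among the results, and Fbxo32 was chosen after its value was seen.

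Further muscle and clock genes changed with the knockdown without stretch. Fbxo32, which encodes atrogin-1, the muscle ligase often studied beside MuRF1, fell by 1.15 (SE 0.0476, adjusted p = 1.58e-17). The lysosomal protease genes Ctsd and Ctsb fell by 0.57 (SE 0.0284) and 0.40 (SE 0.0268), while their list did not pass camera (adjusted p = 0.194), with 7 rises and 13 falls among 30. Among clock genes, Nr1d1 fell by 0.78 (SE 0.0417) and Dbp by 1.12 (SE 0.0676). The clock list did not pass camera (adjusted p = 0.282), with 5 rises and 8 falls among 19.

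Zscan4 genes, which mark a state like that of the 2-cell embryo, were among the largest rises with the knockdown, and a candidate explanation is that a wider set of such transcripts rose together. Of 12 further genes of that stage, 11 rose in both knockdown comparisons, as did 3065 of all 14411 tested genes. Duxf3 was the exception, at -0.06 and 0.01. The list was drawn from symbols seen to be tested, many members had low counts, and reads shared between near-identical members cannot be excluded. Without stretch, Tdpoz5 stood at 0.033 CPM in control and 0.263 CPM in knockdown cells, and Tcstv3 at 0.115 and 0.546 CPM. Such genes passed the count filter only through knockdown libraries, so their rise was largely fixed beforehand. Usp17la, Usp17lb, Usp17lc and Usp17ld are relatives of Usp17le, which was already seen among the rises.

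Trim55 fell with the knockdown, and the hairpin might have matched both genes. Trim63 and Trim55 transcripts shared 0 stretches of 19 identical bases, and the longest shared stretch was 17 bases, which argues against a full match to both. A partial match stays open, as the hairpin sequence is not given in the sources used here.

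Zinc finger (Zfp) genes were among the largest falls with stretch in knockdown cells, and not in control cells, so the group of 331 was tested. In control cells 8 rose and 20 fell, and in knockdown cells 21 rose and 44 fell. The median log2 fold change was -0.011 in control cells, as in the other genes, and -0.037 in knockdown cells against -0.0048 in the others. Camera gave adjusted p of 0.893 and 0.0167 with the preset correlation, and 0.933 and 0.195 with an estimated correlation, which leaves open whether they fell as a group.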
